A study of Caenorhabditis elegans with 36 samples.

How the data were processed

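The 36 samples comprise 8 adult small RNA libraries, 8 embryo small RNA libraries (4 inputs and 4 NRDE-3 IP) and 20 adult RNA-seq libraries. Per the labels' protocols, worms were grown at 20 degrees on HB101 bacteria, small RNA libraries used a 5′-independent method with Illumina TruSeq small RNA reagents, and RNA-seq libraries used NEB NEXT Ultra reagents. Per the submitters' processing notes, small RNA reads were trimmed with cutadapt, all reads were aligned with STAR to the ce11 build, features were counted with featureCounts, and DESeq2 was used for testing. No versions, counting options or strand settings are given there.

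The embryo gene tables hold whole counts per gene as deposited, with no scaling. The adult gene table and all repeat-family tables hold estimated counts as deposited, with fractions where a read was shared between features or positions, as the values show, and these were rounded to whole numbers before testing. The RNA-seq table used here holds repeat families only, so the planned tests of messenger RNA per gene were not run. RNA families were therefore scaled within that table, and not with the factors of a gene table as planned. Families of simple, low-complexity and satellite repeats were left out of the main tests.

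Gene symbols were matched for 28876 of 31003 adult and 43720 of 46740 embryo identifiers, and coordinates, from an annotation of the assembly that ce11 names, for 28632 and 43423. Among genes with a mean of at least 20 counts, 13.7% of adult and 9.35% of embryo genes had the same counts in every library as another gene.

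Groups were taken from the labels. Adult small RNA libraries were fitted together, as were 19 RNA-seq libraries, leaving out the single nip1_nip2 library. Embryo input and IP libraries were fitted apart for the mutant comparisons and together for IP against input. The embryo columns are named wt1, wt2, nip1nip1_1 and nip1nip2_2, which do not match the sample numbers, and nipnip2 is the name in the labels. Tests were the quasi-likelihood F-tests of edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM scaling and Benjamini-Hochberg adjustment, called under 0.05. Small RNA families of transposable elements were scaled with the factors of the gene table. The package data.table (version 1.17.8) read the files.

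The 26 gene lists covered Argonautes, nuclear RNAi and heterochromatin, the 26G-RNA pathway, mutator and 22G-RNA synthesis, piRNA pathway and germ granules, ERGO-1 target loci, histones, major sperm proteins, other sperm genes, oocyte and eggshell, early zygotic genes, germline proliferation and meiosis, vitellogenins, intestine, muscle, neurons, cuticle collagens, molting, lectins and lysozymes, heat shock, pals genes, F-box and MATH-BATH genes, chemoreceptors, ribosomal proteins, microRNAs and 21U-RNAs. Lists with at least 5 tested genes were tested with camera in limma 3.58.1 on log CPM with a prior count of 2, a preset correlation of 0.01, and an estimated correlation as the alternative. The tests, lists, rule for named genes and the alternatives other than those marked below were chosen before the data were examined. The rule took, among called genes with a mean of at least 20 counts and every library of one group above every library of the other, the 8 largest changes per direction (5 in direct comparisons of mutants and in RNA-seq single mutants) and the 4 smallest p per direction. It added 3 members of each called list, 5 Argonaute genes, genes named enri, and 3 families per direction. Which of the genes under the rule are printed was chosen after their values were seen.

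Alternatives were DESeq2 1.42.0, RLE scaling, no low-count filter, a mean of at least 50 counts, a test against a fold of 1.5, scaling to microRNA reads, fits of only the groups compared, 1 fit of all embryo libraries, the replicate number as a block, each library left out, and a list threshold of log2 fold 2 in place of 1. Library totals without TMM factors, a list of genes enriched in the IP by those totals, all repeat families and, for IP against input, the shared column name as a block were added after the data were seen. Overlaps between comparisons with shared controls were set against 20 simulations of unchanged groups. In these all groups, wt included, had the same means, and libraries varied independently. Relations across families were tested with 100000 permutations, two-sided.

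The tests were checked on simulated counts with planted changes, drawn with the same dispersion of 0.05 for every gene and family. That value was set and not estimated from these libraries, so the shares recovered hold for that spread only. At a fold of 4, 80% of planted genes were recovered for nip2nip3 against wt in adults, 91% for nip2nip3 against nip3_qe17, 81% in embryo input, 75% in the IP and 26% for IP against input. At a fold of 2 the shares were 27%, 26%, 9%, 18% and 3%. For families at a fold of 2, 80% were recovered in adult small RNA, 30% in the IP and 60% in RNA of nip2_nip3.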

Results

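Small RNAs and longer RNAs were sequenced from Caenorhabditis elegans carrying mutations named nip1, nip2 and nip3 and from wild type (wt), in a study of candidate factors for the inheritance of RNA silencing between generations. Small RNA libraries of young adults were made with a 5′-independent protocol, which also captures the triphosphorylated secondary small RNAs made by RNA-dependent RNA polymerases. They comprised 2 wt, 3 nip2nip3 double mutant and 3 nip3_qe17 libraries, where qe17 is an allele of nip3. Embryo libraries came from small RNAs immunoprecipitated (IP) with NRDE-3, the somatic nuclear Argonaute, and from input, with 2 libraries each from wt and from a strain labelled nipnip2. Longer RNA of adults was sequenced in 20 libraries from wt and 7 mutant genotypes, and the table used here counts repeat families only. Adult small RNA libraries held 6361904 to 10962034 counts on genes, embryo inputs 1149734 to 2200941 and IP libraries 2957534 to 5957024. The RNA-seq libraries held 31571 to 88398 counts on transposable element families. Nothing states that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Strand was not stated for the counting, so values of overlapping, antisense and near-identical genes, histone and major sperm protein genes among them, are uncertain. Floors given for groups at 0 cover counting error only.

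The labels do not tie the nip names to gene identifiers, so the targeted genes could not be checked as such. The genes annotated as enri-1 and enri-2 were tabulated in every small RNA library. In adults enri-2 had 5 and 9 counts in the wt libraries, 0 in each of the 3 nip2nip3 libraries, and 2, 6 and 2 in nip3_qe17. Counts at enri-1 were 19 and 16 in wt, 8, 15 and 15 in nip2nip3, and 5, 14 and 7 in nip3_qe17. In embryo input enri-1 had 5 and 4 counts in wt and 0 in both nipnip2 libraries, and in all 4 IP libraries it had 0. These counts are near the limit of detection, and the edgeR quasi-likelihood test called neither mutant for enri-1 (Benjamini-Hochberg adjusted p = 0.475 in nip2nip3 and 0.0502 in nip3_qe17).

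To ask which small RNAs depend on nip2 and nip3 together, adult nip2nip3 libraries were compared with wt. Small RNAs at Y110A2AL.1 (chromosome II, 2875101 to 2876768 in ce11) fell from 727 ± 193 normalised CPM (SD, n = 2) in wt to 1.53 ± 0.463 CPM (n = 3) in the mutant, a log2 fold change of -8.88 (SE 0.25). Those at ckk-1, which encodes a calmodulin-dependent kinase kinase (chromosome III, 5635479 to 5654564), fell from 318 ± 14.5 to 4.02 ± 0.296 CPM, and those at dlk-1, a kinase of axon regeneration (chromosome I, 12565800 to 12572801), from 363 ± 11 to 9.61 ± 0.710 CPM. In the opposite direction, counts at ift-20, an intraflagellar transport gene (chromosome I, 5100751 to 5101732), rose from 1.60 ± 0.273 to 374 ± 37 CPM, with a log2 fold change of 7.86 (SE 0.29). W01A11.7 (chromosome V, 6504546 to 6505389) rose from 11.9 ± 1.25 to 523 ± 36.2 CPM. All 5 genes had every mutant library on one side of both wt libraries, and their adjusted p-values were 5.31e-09, 1.81e-09, 1.81e-09, 1.98e-08 and 5.31e-09 in the same order (edgeR quasi-likelihood, Benjamini-Hochberg).

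Further large increases were at Y61A9LA.7 (log2 fold change 6.18, SE 0.17), cutl-26 (log2 fold change 5.66, SE 0.51), tbc-6 (log2 fold change 5.32, SE 0.20) and C02F5.10 (log2 fold change 5.28, SE 0.12). C42D4.19 had 0 counts in both wt libraries and 89 to 137 in the mutant, at least 75.3-fold higher against a floor of 3 counts over the wt group. The lectin gene clec-238 fell by 7.89 on the log2 scale. Of 5 Argonaute genes named before the data were examined, csr-1, the Argonaute of germline-expressed genes, had a log2 fold change of -1.29 (SE 0.11), the piRNA Argonaute gene prg-1 -0.91 (SE 0.11), ergo-1 -0.66 (SE 0.13), nrde-3 -0.82 (SE 0.27) and the germline nuclear Argonaute gene hrde-1 -0.43 (SE 0.10), while the list of all Argonautes was not called. Of 16585 genes tested, 3638 had higher and 3525 lower counts in nip2nip3 (edgeR quasi-likelihood, adjusted p under 0.05), and 8498 had an unadjusted p under 0.05. The balance depended on the scaling, with 2233 higher and 5962 lower by library totals (median shift -0.31) and 1547 higher and 7351 lower when scaled to microRNA reads. Without wt replicate 1 the count was 4435 in place of 7163.

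Among the gene lists fixed before the data were examined, all 30 tested major sperm protein genes rose (median log2 fold change 1.67), as with msp-45 (log2 fold change 2.18, SE 0.19) and msp-3 (log2 fold change 2.15, SE 0.20). The camera test gave adjusted p = 2.43e-14 for this list, and adjusted p = 0.190 with an estimated correlation. Of 43 other sperm genes 25 rose, among them ssp-16 (log2 fold change 1.65, SE 0.17), and 2 fell, among them spe-41 (log2 fold change -1.49, SE 0.13), with camera adjusted p = 7.46e-05 and adjusted p = 0.280 with an estimated correlation. Of 3468 tested 21U-RNA loci, the piRNA genes of the nematode, 944 rose and 56 fell (camera adjusted p = 2.56e-11, adjusted p = 0.0443 with an estimated correlation). Adjusted over the list alone, 694 rose and 41 fell. The median log2 fold change of the 21U-RNA loci was 0.66, but 0.35 by library totals and 0.13 with microRNA scaling. Over all genes tested the median was 0.05, -0.27 and -0.49 in the same order. Members of the F-box and MATH-BATH families, which hold substrate receptors for protein degradation, fell in 144 of 234 cases and rose in 20 (median -1.20, camera adjusted p = 5.04e-13, adjusted p = 0.0124 with an estimated correlation). Examples are fbxa-120 (log2 fold change -4.46, SE 0.13) and fbxa-136 (log2 fold change -4.44, SE 0.14). Adjusted over the list alone, 150 fell and 20 rose. Of 10 tested pals genes 8 fell and 0 rose by the edgeR quasi-likelihood test, among them pals-22 (log2 fold change -2.60, SE 0.11), a repressor of the intracellular pathogen response (camera adjusted p = 0.000201, adjusted p = 0.0956 with an estimated correlation).

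Chemoreceptor genes fell in 33 of 88 cases and rose in 8, with srh-171 at -5.93 (SE 0.29) (camera adjusted p = 0.00263, adjusted p = 0.108 with an estimated correlation). Of 18 genes of nuclear RNAi and heterochromatin 10 fell and 1 rose, including hpl-1, a heterochromatin protein gene (log2 fold change -2.59, SE 0.22, list adjusted p = 0.0187 by camera, adjusted p = 0.181 with an estimated correlation). The mutator and 22G-RNA synthesis list had 11 of 18 lower and 0 higher, including rde-11 (log2 fold change -1.24, SE 0.13, list adjusted p = 0.00203 by camera, adjusted p = 0.211 with an estimated correlation). Of 32 piRNA pathway and germ granule genes 13 fell, such as meg-4 (log2 fold change -3.55, SE 0.25), and 3 rose (camera adjusted p = 0.0423, adjusted p = 0.236 with an estimated correlation). Ribosomal protein genes fell in 17 of 75 cases and rose in none by the edgeR quasi-likelihood test (camera adjusted p = 0.00460, adjusted p = 0.236 with an estimated correlation). Histone genes rose in 19 of 71 cases, such as his-50 (log2 fold change 2.43, SE 0.18), and fell in 3, though the list median of 0.34 turned to -0.20 when scaled to microRNA reads (camera adjusted p = 0.00141, adjusted p = 0.237 with an estimated correlation). Among 11 loci targeted by ERGO-1 26G-RNAs 8 rose and 2 fell, those that rose including B0250.8 (log2 fold change 1.33, SE 0.13) and F55C9.3 (log2 fold change 0.97, SE 0.17), and the median of 0.53 turned to -0.01 with microRNA scaling (camera adjusted p = 0.0494, adjusted p = 0.211 with an estimated correlation). MicroRNA genes rose in 49 of 150 cases and fell in 12, among them mir-258.2 (log2 fold change -3.14, SE 0.18), and their median of 0.50 was 0.18 by library totals (camera adjusted p = 0.00980, adjusted p = 0.236 with an estimated correlation). For these lists too, the median over all genes tested was -0.27 by library totals and -0.49 with microRNA scaling.

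The other 13 lists did not pass. Their higher and lower members were 4 and 11 of 20 Argonautes, 3 and 4 of 14 genes of the 26G-RNA pathway, 0 and 5 of 20 oocyte and eggshell genes, and 1 and 3 of 27 genes of germline proliferation and meiosis. For early zygotic genes they were 1 and 1 of 5, for vitellogenins 1 and 0 of 6, for intestine markers 2 and 1 of 8, for muscle 0 and 2 of 5 and for neurons 3 and 4 of 12. Cuticle collagens had 10 higher and 3 lower of 34, molting genes 2 and 2 of 6, C-type lectins and lysozymes 25 and 13 of 67, and heat shock genes 3 and 5 of 13. Median, mean and test differed in sign for the 26G-RNA pathway (median 0.01, mean 0.10, test lower), early zygotic genes (0.09, 0.12, lower), molting genes (0.03, -0.05, higher) and lectins (0.35, -0.09, higher).

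The single mutant nip3_qe17 was compared with the same wt libraries to ask what the loss of nip3 alone did. Small RNAs at Y110A2AL.1 fell here as well, to 2.16 ± 0.385 CPM (n = 3) from 727 ± 193 CPM (n = 2), as did those at ckk-1, to 10.1 ± 1.25 CPM, and at grd-16, a gene of the Hedgehog-related family (log2 fold change -6.29, SE 0.26). Among the larger increases were W01A11.7 (log2 fold change 5.14, SE 0.14), ift-20 (log2 fold change 4.87, SE 0.28), the predicted peptide receptor gene frpr-13 (log2 fold change 4.54, SE 0.32) and the cell migration gene mig-21 (log2 fold change 4.34, SE 0.16). F53A3.1 rose by 4.17 (SE 0.14) and rgs-3, a regulator of G protein signalling, by 3.81 (SE 0.13) on the log2 scale. The adjusted p of these 9 genes was at most 2.30e-06 (edgeR quasi-likelihood, Benjamini-Hochberg). Of the 16585 genes tested, 2959 rose and 3176 fell, with 1830 higher and 5051 lower by library totals (median shift -0.27) and 1374 higher and 6961 lower when scaled to microRNA reads. Without wt replicate 1 the count was 3820 in place of 6135.

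In this mutant too all 30 major sperm protein genes rose (median 1.44, camera adjusted p = 4.84e-15, adjusted p = 0.264 with an estimated correlation), with msp-45 at 2.0 (SE 0.19). Other sperm genes rose in 24 of 43 cases, such as spe-18 (log2 fold change 1.89, SE 0.18), and fell in 2, such as spe-41 (log2 fold change -1.50, SE 0.13), with camera adjusted p = 4.59e-06 and adjusted p = 0.387 with an estimated correlation. F-box and MATH-BATH genes fell in 139 of 234 cases and rose in 25 (camera adjusted p = 1.41e-12, adjusted p = 0.0135 with an estimated correlation), with fbxa-120 at -3.86 (SE 0.13). Chemoreceptor genes fell in 34 of 88 cases and rose in 6, with srh-171 at -4.85 (SE 0.25) (camera adjusted p = 0.000646, adjusted p = 0.127 with an estimated correlation). Of 10 pals genes 6 fell, with pals-22 at -2.23 (SE 0.10) (camera adjusted p = 0.00447, adjusted p = 0.223 with an estimated correlation). Histone genes rose in 24 of 71 cases and fell in 1, with his-50 at 2.0 (SE 0.18), and the list median of 0.45 turned to -0.03 with microRNA scaling (camera adjusted p = 0.000597, adjusted p = 0.387 with an estimated correlation). With microRNA scaling the median over all genes tested was -0.46. The other 20 lists were not called. Small RNAs fell at csr-1 (log2 fold change -1.24, SE 0.11), prg-1 (log2 fold change -0.79, SE 0.11), ergo-1 (log2 fold change -0.65, SE 0.13) and hrde-1 (log2 fold change -0.34, SE 0.10), while nrde-3 had -0.69 (SE 0.26) with adjusted p = 0.0624 (edgeR quasi-likelihood, Benjamini-Hochberg).

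The mutants shared 2488 higher and 2706 lower genes, and 38 genes were called in opposite directions. Independent lists of these sizes would share 649 and 675 genes. In 20 simulations with no change in any group, wt included, 0.05 genes on average were shared in each direction. With almost nothing to call there, this number does not show what the shared wt libraries add to real calls. Across genes, which are not independent replicates, the 2 sets of fold changes had a Pearson correlation of 0.901 against 0.604 in the simulations. Their covariance was 1.33 against 0.0783, a difference of 1.25. The 2 wt libraries could not be split, so part of the excess overlap may come from the shared controls.

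X-linked protein-coding genes stood apart in both adult mutants. In nip2nip3 the median log2 fold change of 990 X-linked genes was -1.15, against -0.13 for autosomal genes, and 556 of them (56.2%) fell while 79 rose (edgeR quasi-likelihood, adjusted p under 0.05). On the autosomes 20.3% (chromosome IV) to 27.6% (chromosome V) of genes fell. In nip3_qe17 the X-linked median was -1.19 against -0.03, with 561 genes (56.7%) lower and 61 higher, and 16% to 24% of genes fell on the autosomes. Leaving out each library in turn gave X-linked medians of -1.30 to -1.10 in nip2nip3 and -1.23 to -1.17 in nip3_qe17. By library totals the X-linked median was -1.46 in each mutant. In the same libraries the major sperm protein genes had medians of 1.67 and 1.44 and other sperm genes 0.93 and 0.81. In nipnip2 embryos the X-linked median was instead above those of the autosomes. In input it was 0.19 against 0.02 to 0.06, with 26 of 456 genes higher and 14 lower, against 0.962% to 1.42% higher on the autosomes. In the IP it was 0.58 against 0.21 to 0.51, with 51 of 213 genes higher (23.9%, against 8.76% to 12.3%) and 34 lower (edgeR quasi-likelihood, adjusted p under 0.05).

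**Figure D1:**
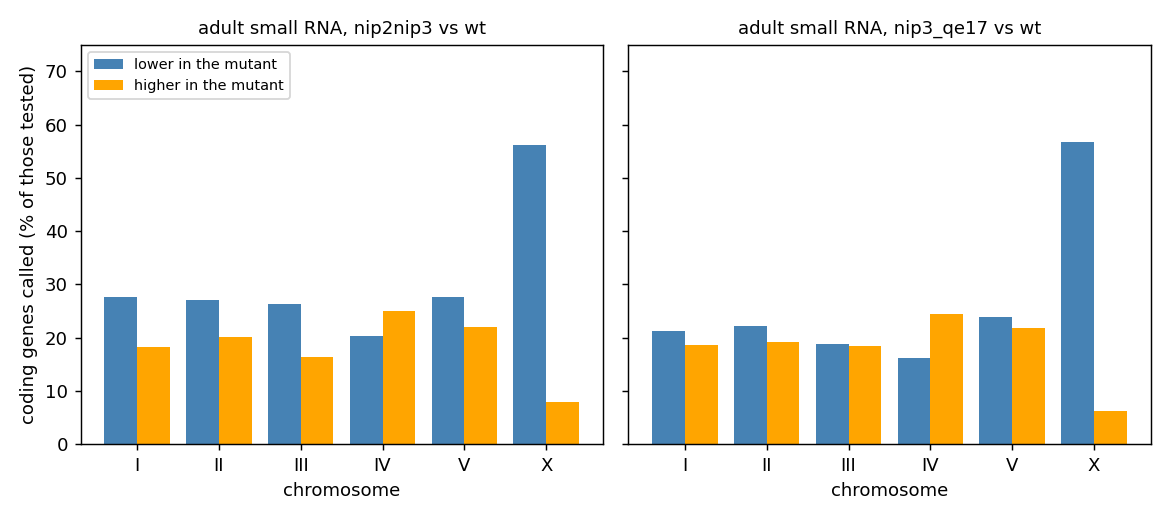
Percentage of protein-coding genes tested on each chromosome whose small RNA counts were called lower (blue) or higher (orange) in adult nip2nip3 and nip3_qe17 against wt. On chromosome X 56.2% and 56.7% were lower, and on no autosome more than 27.6% were.

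The double mutant was then compared directly with nip3_qe17, which tests the difference between their effects. Small RNAs at rdl-1 (chromosome IV, 7768227 to 7770262) were higher in nip2nip3, at 223 ± 8.24 CPM (SD, n = 3) against 7.46 ± 0.428 CPM (n = 3), as were those at the ciliary gene bbs-5 (chromosome III, 10258831 to 10261782), at 556 ± 7.17 against 31.5 ± 1.38 CPM, and at C02F5.10, at 430.4 ± 4.47 against 19.5 ± 0.852 CPM. Increases also included cutl-26 (log2 fold change 6.70, SE 0.48), tbc-6 (log2 fold change 4.97, SE 0.16) and the peroxisome gene prx-11 (log2 fold change 3.42, SE 0.11). Lower in the double mutant were trp-4, a mechanosensory channel gene, at 3.23 ± 0.659 against 95.6 ± 13.6 CPM, cls-3 (log2 fold change -4.02, SE 0.37), C27D8.3 (log2 fold change -3.41, SE 0.13) and the homeobox gene ceh-20 (log2 fold change -2.06, SE 0.09). The largest adjusted p of these 10 genes was 9.95e-05 (edgeR quasi-likelihood, Benjamini-Hochberg). In total 451 genes were higher and 244 lower, and 3068 had an unadjusted p under 0.05. Without nip3_qe17 replicate 3 the count of 695 became 372, and without nip2nip3 replicate 2 it became 412.

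Of the 21U-RNA loci 178 were higher in the double mutant and 1 lower, with 21ur-5387 at 1.79 (SE 0.13), and adjusted over the list alone 260 were higher and 2 lower (camera adjusted p = 2.37e-18, adjusted p = 0.0271 with an estimated correlation). The share of counts at these loci was 3.28% in nip3_qe17 replicate 1, 4.26% and 4.21% in its replicates 2 and 3, and 4.69% to 5.15% in nip2nip3. MicroRNAs were higher in 12 of 150 cases, including cel-mir-62 (log2 fold change 1.40, SE 0.17), and lower in 3 (camera adjusted p = 0.0201, adjusted p = 0.391 with an estimated correlation). Cuticle collagens were higher in 4 of 34 cases, including dpy-17 (log2 fold change 1.86, SE 0.16, list adjusted p = 0.00428 by camera, adjusted p = 0.146 with an estimated correlation). Major sperm protein genes had a median of 0.22 with none of 30 called by the edgeR quasi-likelihood test, at a camera adjusted p of 0.00654 and adjusted p = 0.600 with an estimated correlation. The remaining 6 called lists had negative medians of small size. They were germline proliferation and meiosis (-0.19, camera adjusted p = 0.000210, adjusted p = 0.146 with an estimated correlation), nuclear RNAi and heterochromatin (-0.14, 0.00950 and 0.146), and piRNA pathway and germ granules (-0.08, 0.00994 and 0.177). The last 3, with the same 3 values, were pals genes (-0.36, 0.0105 and 0.177), oocyte and eggshell genes (-0.10, 0.0114 and 0.468) and mutator and 22G-RNA synthesis (-0.13, 0.0189 and 0.391). In those 6 lists the single calls were prde-1, a piRNA transcription factor gene (log2 fold change -0.53, SE 0.09), and 1 pals gene, both lower.

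The embryo IP was first compared with its input to define the small RNAs bound by NRDE-3. In wt embryos the IP was enriched for small RNAs at Y110A2AL.4 (chromosome II, 2839304 to 2840386; log2 fold change 8.3, SE 0.44, n = 2 and 2), K02C4.5 (log2 fold change 7.96, SE 0.41), linc-86 (log2 fold change 7.86, SE 0.36) and fbxc-19 (log2 fold change 7.48, SE 0.36), with adjusted p at most 3.50e-16 (edgeR quasi-likelihood, Benjamini-Hochberg). The size of these changes rests on the scaling, and by library totals they were 3.24, 2.89, 2.79 and 2.41 in the same order. Histone genes were enriched in 66 of 69 cases, with his-45 at 5.60 (SE 0.31) and a list median of 4.5 that turned to -0.54 by library totals (camera adjusted p = 3.00e-46, adjusted p = 0.0636 with an estimated correlation). Among 11 ERGO-1 target loci 10 were enriched and 1 depleted, those enriched including C44B11.6 (log2 fold change 6.42, SE 0.35), F55C9.5 (log2 fold change 6.21, SE 0.34) and F52D2.6 (log2 fold change 5.88, SE 0.31; 1.35, 1.15 and 0.81 by library totals), with a median of 5.45 that turned to -0.97 when scaled to microRNA reads (camera adjusted p = 4.01e-11, adjusted p = 0.331 with an estimated correlation). Over all genes tested the median was -5.45 by library totals and -6.83 with microRNA scaling, so the histone and ERGO-1 medians stayed above it. The other 20 lists tested were not called, and for F-box and MATH-BATH genes the median was -0.62, the mean 0.18 and the direction of the test higher. The nrde-3 locus itself was enriched (log2 fold change 3.40, SE 0.27) on the main scaling but had -1.66 by library totals, and csr-1, hrde-1 and prg-1 were depleted (-2.18, -1.56 and -1.31). The synaptic gene cla-1 had 1373 and 1453 counts in input and 0 in both IP libraries, at least 69.3-fold lower against a floor of 3 counts over the IP group.

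In nipnip2 embryos the enriched genes included K02C4.5 at 9.02 (SE 0.48), fbxa-66 at 7.86 (SE 0.41), fbxc-19 at 7.70 (SE 0.37), Y110A2AL.4 at 7.59 (SE 0.43), F39E9.6 at 7.58 (SE 0.46) and linc-86 at 7.30 (SE 0.37), which by library totals had 5.22, 4.03, 3.85, 3.76, 3.73 and 3.45. Of 9249 genes tested, 1083 were higher and 1182 lower in the wt IP than in its input, and 1464 higher and 1356 lower in the nipnip2 IP. These splits rest on the scaling. By library totals they were 189 and 8810 in wt (median shift -4.91) and 245 and 8589 in nipnip2 (median shift -3.82), and with microRNA scaling 13 and 8998, and 15 and 9012. Without the wt IP library in the column named wt2, the wt count of 2265 became 1380.

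A list of 1075 genes enriched at least 2-fold in the wt IP with TMM scaling was carried to the adults, where 959 were tested. In nip2nip3 173 of them rose and 190 fell, with a median log2 fold change of 0.03 against 0.05 for the other genes. In nip3_qe17 176 rose and 210 fell, with a median of 0.04 against 0.01, and between the mutants 21 were higher and 11 lower. The camera test against other genes gave adjusted p = 0.959 in each of the 3 comparisons (limma, Benjamini-Hochberg over the 3). The fry test of a shift in one direction gave adjusted p = 0.739, 0.153 and 0.153 in the same order. A stricter list of 874 genes, 764 of them tested, had medians of 0.10, 0.01 and 0.06 and camera adjusted p = 0.802, 0.904 and 0.746 (limma). With fry it gave adjusted p = 0.0257, 0.252 and 0.0163, though by library totals its medians were -0.21, -0.27 and 0.02, so that the direction in nip2nip3 turned with the scaling. The list itself rests on the scaling too, and by library totals it held 138 genes, 108 of them tested. Their medians were 0.27, 0.15 and 0.09, or -0.04, -0.13 and 0.05 with the adult changes by library totals. Camera gave adjusted p = 0.465, 0.691 and 0.465 and fry adjusted p = 0.531, 0.531 and 0.515 (limma, Benjamini-Hochberg over the 3).

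Embryo input of nipnip2 was compared with wt input. Small RNAs fell at wdr-62 (chromosome V, 9444048 to 9460669) from 76.8 ± 3.96 CPM (SD, n = 2) to 2.82 ± 0.328 CPM (n = 2), and at the selenophosphate synthetase gene seld-1 (chromosome IV, 13506079 to 13509215) from 284 ± 39.5 to 24 ± 2.65 CPM. They rose at T28D6.4 (chromosome III, 11360456 to 11366198) from 4.59 ± 1.43 to 153 ± 4.4 CPM, at prx-11 from 5.81 ± 1.07 to 79.0 ± 19.8 CPM and at anc-1, which encodes a giant nuclear anchorage protein, from 98.5 ± 36.3 to 651 ± 118 CPM. Others that rose were cdk-14 (log2 fold change 3.39, SE 0.34) and C09G5.7 (log2 fold change 3.33, SE 0.26), and C30G12.4 went from 0 counts to 70 and 105, at least 55.5-fold. Others that fell were faah-2 (log2 fold change -3.90, SE 0.52), kel-8 (log2 fold change -3.80, SE 0.38) and fmil-1 (log2 fold change -3.79, SE 0.70). Adjusted p-values were 0.000159 for wdr-62 and seld-1, 0.000111 for T28D6.4, and at most 0.0139 for the rest (edgeR quasi-likelihood, Benjamini-Hochberg).

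Of 11 ERGO-1 target loci 9 fell and none rose by the edgeR quasi-likelihood test, with a median of -1.53 that was -0.96 by library totals and -0.00 with microRNA scaling, including C44B11.6 (log2 fold change -2.93, SE 0.26), K02E2.6 (log2 fold change -2.39, SE 0.21) and F52D2.6 (log2 fold change -1.54, SE 0.19), with camera adjusted p = 1.29e-08 and adjusted p = 0.959 with an estimated correlation. Adjusted over the list alone, 10 of them fell. F-box and MATH-BATH genes fell in 26 of 178 cases, among them fbxa-53 (log2 fold change -3.28, SE 0.41), math-20 (log2 fold change -3.03, SE 0.39) and fbxb-37 (log2 fold change -1.76, SE 0.24), and rose in 2, but the list median of -0.12 turned to 0.46 by library totals (camera adjusted p = 0.00535, adjusted p = 0.959 with an estimated correlation). The histone list had a median of -0.33, which turned to 0.25 by library totals, with his-15 (log2 fold change -1.17, SE 0.24) the single call (camera adjusted p = 0.00201, adjusted p = 0.906 with an estimated correlation). Ribosomal protein genes had a median of 0.14 with none of 64 called by edgeR (camera adjusted p = 0.0242, adjusted p = 0.969 with an estimated correlation). Over all genes tested the median was 0.58 by library totals and 1.53 with microRNA scaling. The ERGO-1, F-box and histone medians lay below it on both. The other 18 lists tested were not called, and csr-1, prg-1, hrde-1, nrde-3 and ergo-1 were not called either, with log2 fold changes of -0.10 to 0.42. Of 8506 genes tested 109 rose and 434 fell (47 and 291 with DESeq2, 185 and 834 with no low-count filter), and 1572 had an unadjusted p under 0.05. By library totals 1474 rose and 290 fell (median shift 0.58), with microRNA scaling 6955 rose and 115 fell, and without the input library in the column named nip1nip1_1 the count of 543 became 921.

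To ask which NRDE-3-bound small RNAs changed in nipnip2 embryos, the IP libraries were compared. Small RNAs of linc-22, a long intergenic RNA gene (chromosome X, 9069138 to 9073735), made up 11.9 ± 0.281% of wt IP counts (SD, n = 2) and 7.15 ± 1.87% of nipnip2 IP counts (n = 2), the largest share of any gene in wt. In input its share was 6.71 ± 1.03% in wt and 2.0 ± 0.585% in nipnip2 (n = 2 each), and that of linc-11 0.753 ± 0.286% and 0.230 ± 0.0230%. Both genes also fell in the test of input (log2 fold change -2.29, SE 0.34, adjusted p = 0.00498, and log2 fold change -2.27, SE 0.30, adjusted p = 0.00304). The change of IP over input of linc-22 was not called (log2 fold change -0.22, SE 0.48, adjusted p = 0.920), and by library totals it was 1.0 with adjusted p = 0.0458. In the scaled test linc-22 fell by 2.64 on the log2 scale and linc-11 by 2.71, with adjusted p = 1.94e-69 and 1.15e-51 (edgeR quasi-likelihood, Benjamini-Hochberg), but with microRNA scaling neither was called (-0.57 and -0.60, adjusted p = 0.254 and 0.267). With 2 libraries per group the test borrows its spread from other genes. Such small p-values therefore do not measure the spread at these genes alone. The microRNA scaling of embryo libraries rests largely on mir-260 and cel-mir-8199. In the wt IP these held 2.64 ± 1.25% and 0.827 ± 0.0618% of counts, against 0.848 ± 0.0823% and 0.335 ± 0.00140% in wt input. Values with that scaling thus depend on these loci and are no neutral check. On the main scaling, larger decreases than at linc-22 and linc-11 were at clec-166 (log2 fold change -4.7, SE 0.46), fbxa-53 (log2 fold change -4.44, SE 0.33), math-40 (log2 fold change -4.35, SE 0.38), linc-25 (log2 fold change -4.18, SE 0.34) and math-20 (log2 fold change -4.16, SE 0.37). Small RNAs rose at spt-5, a transcription elongation factor gene (log2 fold change 2.78, SE 0.49), at hlh-30, a transcription factor gene of autophagy and lysosomes (log2 fold change 2.36, SE 0.37), and at lron-11 (log2 fold change 2.28, SE 0.48), rnst-2 (log2 fold change 2.25, SE 0.56), mml-1 (log2 fold change 2.15, SE 0.49) and K10B3.5 (log2 fold change 1.99, SE 0.35). Those at cla-1 went from 0 counts to 26 and 57, at least 11.9-fold higher against a floor of 3 counts over the wt group. Small RNAs at ergo-1 rose (log2 fold change 1.65, SE 0.59), and those at nrde-3, hrde-1, csr-1 and prg-1 were not called. The ergo-1 counts were 2 and 5 in the wt IP and 22 and 29 in the nipnip2 IP. These are near the limit of detection, so the size of the change is uncertain.

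Histone genes fell in 65 of 67 cases, with his-68 at -3.07 (SE 0.39), and the list median of -2.04 became -0.13 by library totals and turned to 0.03 with microRNA scaling (camera adjusted p = 1.04e-21, adjusted p = 0.551 with an estimated correlation). Of 11 ERGO-1 target loci 10 fell, including C44B11.6 (log2 fold change -3.63, SE 0.26), K02E2.6 (log2 fold change -2.64, SE 0.24) and Y37E11B.2 (log2 fold change -2.04, SE 0.20), and the median of -2.04 became -0.12 by library totals and turned to 0.04 with microRNA scaling (camera adjusted p = 1.09e-05, adjusted p = 0.551 with an estimated correlation). F-box and MATH-BATH genes fell in 39 of 78 cases, with fbxa-51 at -3.62 (SE 0.29), and rose in 6, but the median of -0.93 turned to 0.98 by library totals (camera adjusted p = 0.000255, adjusted p = 0.572 with an estimated correlation). Of 17 tested 21U-RNA loci 13 fell, and their median of -1.91 was -0.00 by library totals and turned to 0.12 with microRNA scaling (camera adjusted p = 0.000168, adjusted p = 0.551 with an estimated correlation). Over all genes tested the median was 2.09 by library totals and 2.33 with microRNA scaling, and the medians of these lists lay below it on both. The other 11 lists tested were not called.

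Fewer genes were detected in the wt IP. Its libraries had 1192 and 1439 genes with at least 10 counts, and the nipnip2 libraries 2983 and 2412, while the 10 most counted genes held 43.7 ± 1.85% and 47.1 ± 0.458% of counts (n = 2 each). TMM factors were 0.515 ± 0.0234 in wt and 1.95 ± 0.0907 in nipnip2, so that values from this comparison are relative to the bulk of genes in each IP. Of 2620 genes tested 265 rose and 614 fell (62 and 440 with DESeq2). By library totals 2029 rose and 146 fell (median shift 1.90), and with microRNA scaling 1973 rose and 58 fell.

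**Figure D2:**
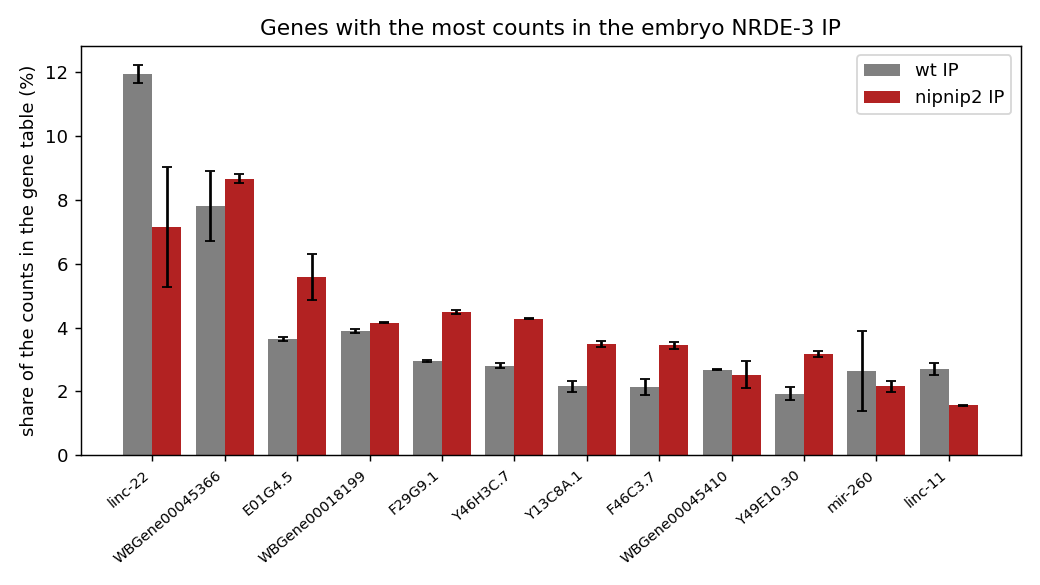
Share of the counts of the embryo NRDE-3 IP libraries, in percent, taken by each of the most counted genes in wt (grey) and nipnip2 (red), as means with SD of 2 libraries. The share of linc-22 averaged 11.9% in wt and 7.15% in nipnip2.

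The change of IP over input was compared between nipnip2 and wt, which tests whether binding relative to input differed. Relative enrichment was lower in nipnip2 for Y54F10BM.9 (chromosome III, 2295328 to 2304927; log2 fold change -2.82, SE 0.36), fbxa-63 (log2 fold change -2.59, SE 0.39), fbxa-13 (log2 fold change -2.54, SE 0.42) and his-68 (log2 fold change -2.38, SE 0.54). It was higher for spt-5 (log2 fold change 2.35, SE 0.53), F54B3.1 (log2 fold change 2.18, SE 0.47) and vet-6 (log2 fold change 1.45, SE 0.37). Adjusted p-values ranged from 3.44e-05 for Y54F10BM.9 to 0.0484 for vet-6 (edgeR quasi-likelihood, Benjamini-Hochberg, n = 2 in each of the 4 groups). In all 5 genes were higher and 76 lower of 9249 tested, and 955 had an unadjusted p under 0.05, while DESeq2 gave 36 higher and 159 lower. By library totals 1636 were higher and 9 lower (median shift 1.11), and with microRNA scaling 1 gene was higher and 0 lower. The count rested on single libraries: without the IP library wt1 it was 11, without the IP libraries nip1nip1_1 and nip1nip2_2 it was 10 and 14, and without the inputs of those names 142 and 53.

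Small RNAs at transposable element families fell more often than they rose in adults. In nip2nip3 Mirage1_CB fell by 4.14, DNA-3-1_CE by 3.88 and MUDR3_CB by 5.12 on the log2 scale, while TC2 (log2 fold change 2.20, SE 0.14), the LTR of the retroelement CER6 (log2 fold change 2.06, SE 0.21) and DIRS-1_CB (log2 fold change 2.01, SE 0.14) rose. In nip3_qe17 Mirage1_CB (log2 fold change -4.10, SE 0.43), DNA-3-1_CE (log2 fold change -3.97, SE 0.25) and CeRep4 (log2 fold change -3.61, SE 0.18) fell and CER6-LTR_CE rose (log2 fold change 2.22, SE 0.21). Adjusted p-values of these families were at most 0.000279 (edgeR quasi-likelihood, Benjamini-Hochberg). Of 188 families tested 39 rose and 93 fell in nip2nip3, and 23 rose and 100 fell in nip3_qe17. By library totals the numbers were 16 and 117 (median shift -0.31), and 10 and 130 (median shift -0.28), and with microRNA scaling 9 and 133, and 9 and 150.

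In nipnip2 embryos small RNAs at MAR_CE fell in input (log2 fold change -2.69, SE 0.29) and in the IP (log2 fold change -4.08, SE 0.31), as did those at Helitron1_CE (log2 fold change -2.20, SE 0.15 in input and log2 fold change -3.01, SE 0.42 in the IP). CER7-LTR_CE fell in input (log2 fold change -1.96, SE 0.16) and CER13-I_CE in the IP (log2 fold change -3.60, SE 0.31), while TIR9TA1_CE (log2 fold change 0.52, SE 0.14) and TC2 (log2 fold change 0.44, SE 0.14) rose in input, though DESeq2 called neither of the last 2. Of 155 families tested in input 2 rose and 12 fell, and by library totals 67 rose and 5 fell (median shift 0.58), with 139 and 1 on microRNA scaling. In the IP 24 families fell and 0 rose by edgeR (35 at an unadjusted p under 0.05), DESeq2 gave 16 lower and 0 higher, library totals 83 higher and 3 lower (median shift 1.91), and microRNA scaling 83 and 2. The input count of 14 became 0 without the library wt1, and 3 and 7 without nip1nip1_1 and nip1nip2_2. The IP count became 8 without wt2 and 12 without nip1nip1_1.

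RNA of repeat families was compared between adult genotypes and wt. The internal region of the retroelement CER9, with 35, 70 and 37 counts in wt, had 956, 942 and 936 in nip1_nip2_nip3 (log2 fold change 4.31, SE 0.83), 611, 1628 and 944 in nip2_nip3 (log2 fold change 4.56, SE 0.84), 53, 723 and 1323 in nip3_qe17 (log2 fold change 3.79, SE 0.81) and 1015 and 318 in nip3_qe20 (log2 fold change 3.64, SE 0.84). In the single mutants nip1_tb1601 and nip2_tb1609 it had 59 and 48, and 51, 88 and 74 counts. The internal region of CER6 had 0 counts in all 3 wt libraries. It rose at least 9.78-fold in nip1_nip2_nip3, 7.75-fold in nip2_nip3, 6.30-fold in nip3_qe20 and 8.40-fold in nip1_tb1601, against a floor of 3 counts over the wt group, and had 9 to 18 counts in nip3_qe17, where it was also called. TR5 rose in the triple mutant (log2 fold change 4.7, SE 0.87), nip2_nip3 (log2 fold change 3.61, SE 0.92) and nip3_qe20 (log2 fold change 4.16, SE 0.93), as did CER2-1-LTR_CE and CER12-LTR_CE. In wt TR5 had 0 to 2 counts, CER2-1-LTR_CE 2 to 4 and CER12-LTR_CE 1 to 3, so the sizes of these changes are uncertain. TR5 also had 4 to 9 counts in nip1_tb1601, 7 to 14 in nip2_tb1609 and 7 to 26 in nip3_qe17, where it was not called. The adjusted p was 0.00814 for CER9-I_CE in the triple mutant, 0.00333 in nip2_nip3, 0.0228 in nip3_qe17 and 0.0221 in nip3_qe20 (edgeR quasi-likelihood, Benjamini-Hochberg).

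Turmoil2 fell in nip2_nip3 (log2 fold change -1.86, SE 0.34), nip1_tb1601 (log2 fold change -1.96, SE 0.38) and nip2_tb1609 (log2 fold change -1.96, SE 0.34). CER15-I_CE fell in the triple mutant (log2 fold change -1.53, SE 0.44) and nip2_nip3 (log2 fold change -2.29, SE 0.48), NeSL-4_CRem fell in the triple mutant (log2 fold change -1.76, SE 0.39), and MIRAGE1 rose in nip2_nip3 (log2 fold change 3.43, SE 0.44). Of 165 families tested, those higher and lower were 10 and 2 in nip1_nip2_nip3 (3 and 0 by totals of the table), 6 and 2 in nip2_nip3, 2 and 0 in nip3_qe17, 9 and 0 in nip3_qe20 (2 and 0 by totals), 1 and 1 in nip1_tb1601 (0 calls by totals) and 0 and 1 in nip2_tb1609 (0 calls by totals), by the edgeR quasi-likelihood test. Unadjusted p-values under 0.05 were found for 35, 31, 23, 32, 15 and 9 families in that order. Totals of the table shifted the median by -0.19, -0.30, 0.03, -0.30, 0.13 and -0.41 in the same order. RNA-seq libraries of different genotypes deviated together from their group means. Replicate 1 of nip2_nip3 had correlations of 0.844 with nip3_qe20 replicate 2, 0.761 with nip3_qe17 replicate 2 and 0.725 with nip2_tb1609 replicate 1. In it 83375 of 86727 repeat counts lay on transposable element families, against 36994 of 54450, 49179 of 84199 and 31571 of 56052 in wt. High shares were also found in nip3_qe20 replicate 2 (70336 of 73361), nip2_tb1609 replicate 1 (88398 of 99572), nip3_qe17 replicate 2 (55051 of 63751) and triple mutant replicate 2 (52593 of 65609). Other libraries of these genotypes had lower shares. No wt library had so large a share, so it is partly confounded with genotype. The tests held no term for these deviations or shares, and their cause was not tested. The counts of calls are small and moved with the fit and with single libraries. Fits of only the groups compared gave 31, 4, 0, 1, 28 and 1 calls in the same order, 65 in sum in place of 34, and DESeq2 gave 5 in nip3_qe17 and 14 in nip3_qe20. The 2 calls of nip3_qe17 became 9 without its replicate 1 and 0 without wt replicates 2 or 3, and the 9 calls of nip3_qe20 became 4 without its replicate 2 and 0 without any of the wt libraries. In the triple mutant the 12 calls became 7 and 6 without its replicates 1 and 3, and 4, 4 and 6 without wt replicates 1, 2 and 3. The call of nip2_tb1609 was lost without its replicate 2, and the 2 calls of nip1_tb1601 became 0 without either of its libraries or wt replicate 3, and 1 without wt replicates 1 or 2. Leaving out any 1 wt library took the sum over the 6 genotypes from 34 to 13, 12 and 13.

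**Figure D3:**
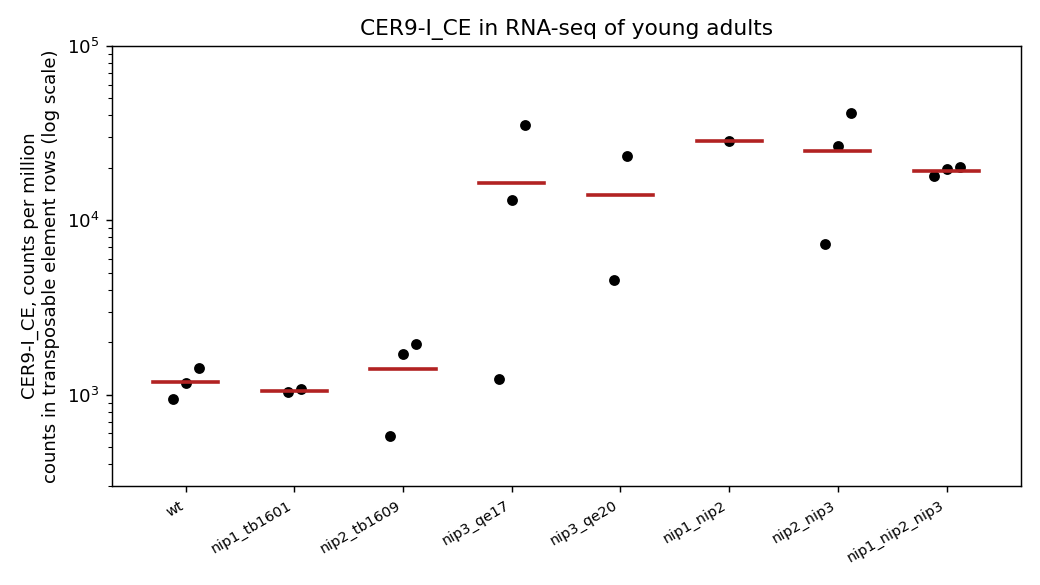
RNA level of the internal region of CER9 in CPM of the counts on transposable element families, on a log axis, with each point an adult library and each line a genotype mean. The 3 wt libraries average 1180 CPM, and nip3_qe17 holds 1 library near wt and 2 far above it.

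Called families overlapped between some genotypes. The triple mutant and nip2_nip3 shared 5 higher families and 1 lower, against 0.364 and 0.0242 for independent lists and 0.05 and 0 in simulations with the shared wt libraries. The triple mutant and nip3_qe20 shared 6 higher families, against 0.545 and 0.05. Correlations of fold changes across the 165 families, which are not independent replicates, were 0.892 and 0.858, against 0.506 and 0.442 simulated. These were the 2 pairs with most families in common. The simulations held no change in any group and no deviations shared between libraries. They therefore set no bound on overlaps or correlations that arise from such sources. Of the 15 pairs of genotypes 3 shared no called family by edgeR, namely nip2_tb1609 with the triple mutant, nip3_qe17 and nip3_qe20. Correlations with nip1_tb1601 were 0.361 for nip2_nip3 and 0.436 for nip2_tb1609, below the simulated 0.448 in each case, and 0.439 for the triple mutant against 0.436. The covariances of these pairs were 0.303, 0.210 and 0.360 in the same order, above the simulated 0.142, 0.125 and 0.128. For the triple mutant with nip2_nip3 and with nip3_qe20 the covariances exceeded the simulated ones by 0.774 and 0.824. Part of the overlap may come from the shared controls, since 3 wt libraries cannot be split into groups of 2. Compared directly, the triple mutant had less MIRAGE1 (log2 fold change -2.65, SE 0.42) and more Turmoil2 (log2 fold change 1.65, SE 0.34) than nip2_nip3, with adjusted p = 0.00199 and 0.0148 (edgeR quasi-likelihood, Benjamini-Hochberg). The 2 calls became 1 without triple mutant replicate 1 or nip2_nip3 replicates 1 or 3, and 0 by totals of the table (median shift 0.11). A fit of only the groups compared also gave 0, and another split of the same 6 libraries gave 7. The alleles nip3_qe17 and nip3_qe20 differed in 0 families by edgeR and in 0 by DESeq2, and 6 families had an unadjusted p under 0.05.

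To compare small RNAs with RNA, fold changes of the 150 families measured in both assays were set against each other. In nip2nip3 Spearman's rho was -0.0725 (permutation p = 0.376) and Pearson's r -0.105 (permutation p = 0.198). In nip3_qe17 rho was -0.102 (p = 0.213) and r -0.0708 (p = 0.373), by permutation tests over 100000 resamples, and Benjamini-Hochberg adjustment over the 2 mutants left rho at 0.376 and r at 0.373. Among families called in small RNA, rho was -0.118 and r -0.140 in nip2nip3 (106 families, adjusted p = 0.230 and 0.150) and -0.171 and -0.206 in nip3_qe17 (100 families, adjusted p = 0.177 and 0.0788). Families are not independent replicates. Of 7 families called in RNA of nip2_nip3, 5 were also called in small RNA, where 106 of the 150 were (Fisher's exact test, p = 1), and in nip3_qe17 neither of the 2 was, against 100 of 150 (p = 0.110). The internal region of CER9 itself had small RNA changes of 0.35 (SE 0.08) in nip2nip3 and -0.02 (SE 0.08) in nip3_qe17, while small RNAs fell at MIRAGE1 (log2 fold change -1.09, SE 0.10) and CER12-LTR_CE (log2 fold change -1.59, SE 0.12) in nip2nip3.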

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

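Of the tests below, those of somatic lists, muscle and neuron genes, wt background, carry-over, the most counted genes, and both for the RNA library were chosen after the result was seen. No group held 4 or more samples, so no test for single outlying samples was made.

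3 direct tests of a difference between groups gave calls by edgeR. IP over input differed between nipnip2 and wt at 81 genes, and the adult small RNAs of nip2nip3 and nip3_qe17 at 695. RNA of the triple mutant and nip2_nip3 differed at 2 families. For the 695 genes, the highest of the other splits of the 6 libraries gave 0, and 1 of 10 splits, the real one, gave as many. The real and highest other values were 12 and 0 for RNA of the triple mutant (1 split as large), 8 and 0 for nip2_nip3 (1), 2 and 2 for nip3_qe17 (2), 1 and 0 for nip2_tb1609 (1), and 2 and 7 for the triple mutant against nip2_nip3 (2). With 10 splits the share of splits as large is never under 0.05.

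The single nip1_nip2 RNA-seq library, which entered no test, lay above every wt library in CPM at 11 of the 14 families called higher in a mutant, and within the wt range at CELE46A, HAT2_CE and Helitron1_CE. Of 3 families called lower it lay below every wt library at NeSL-4_CRem and CER15-I_CE and within the range at Turmoil2. Of families called higher in at least 3 genotypes it held 1126 counts of CER9-I_CE, 21 of CER2-1-LTR_CE, 11 of CER12-LTR_CE, 10 of TR5 and 9 of CER6-I_CE. For CER9-I_CE this is 28386 CPM against 1180 ± 239 CPM (SD, n = 3) in wt. There is no replicate of this library.

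X-linked genes had lower small RNA counts in both adult mutants, with medians of -1.15 and -1.19. Noise at low counts is argued against, since among genes with a mean of at least 50 counts the X-linked median lay -1.34 from the autosomal one in nip2nip3. For a smaller share of all somatic RNA, small RNA counts in nip2nip3 were taken at 55 autosomal genes of the intestine, muscle, neuron and collagen lists. Their median change was 0.172 (bootstrap interval -0.0793 to 0.578). Of these, 6 intestine genes had a median of 0.940 (0.0270 to 1.99) and 33 collagens 0.260 (0.0524 to 0.698). Small RNA counts do not measure the RNA of these genes, and most of the 55 are collagens, so this explanation stays open. A smaller share of muscle and neuron RNA stays open, since the 16 genes of these lists had a median of -0.258 (-1.29 to 0.0835), with -0.80 for 5 muscle and -0.23 for 11 neuron genes, too few to decide. In nip3_qe17 the medians were -0.97 and -0.37. All 30 major sperm protein genes rose in both mutants (medians 1.67 and 1.44), as did 25 and 24 of 43 other sperm genes (medians 0.93 and 0.81), and a change in the share of sperm or germline RNA was not tested. In nipnip2 embryo input the X-linked median was 0.19, above those of the autosomes. A difference in batch or strain background of the wt libraries may also give the pattern. The mutants differed from each other by 0.0920 at X-linked genes, which a shared effect of the mutations and a wt difference would both give, and with 2 wt libraries as the only controls these cannot be told apart.

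More genes were detected in the nipnip2 IP than in the wt IP. Depth is argued against: thinned to 2957534 counts, the wt libraries had 900 and 817 genes with at least 10 counts and the nipnip2 libraries 2619 and 2412, a ratio of 2.93. A larger share on the 10 most counted genes in wt is argued against, since that share was -3.42 percentage points in wt relative to nipnip2. This covers those 10 genes only, and whether the wt counts were concentrated in a larger set of genes was not tested. Carry-over of input RNA stays open and could raise all genes alike: the lowest median change of IP over input, by library totals, was 0.508 in 5 lists of at least 5 genes, against 1.33 over all genes. That minimum was set after the muscle list, with 4 genes, was seen at -0.56, which carry-over would not give, and the intestine list of 2 genes had 1.07. A change in what NRDE-3 binds in the mutant was likewise not tested as a cause of the difference in genes detected.

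RNA of CER9-I_CE was near the wt level in nip3_qe17 replicate 1, with 53 counts against 723 and 1323 in the others. Low depth is argued against by a ratio of 0.923 in counts on transposable element families to the median of the other replicates. A wrong label could also give it: the other families called in the triple mutant and nip3_qe20 had a median change of 0.905 in replicate 1, against 2.44 and 2.77 in replicates 2 and 3, 1.59 and 1.3 in nip1_tb1601, 0.177 to 0.304 in nip2_tb1609, -0.0473 to 0.138 in wt and 2.57 in the single nip1_nip2 library. Replicate 1 thus lay above every wt and nip2_tb1609 library and below the others. Its value lies between the bounds set for the test, so a wrong label and variable expression of the element cannot be told apart.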

How the results depend on the processing

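The choices of library totals, also for the list of genes enriched in the IP, of all repeat families and of the embryo column name as a block were made after the data were seen, and the other alternatives before. Of 2632 values for 198 named genes and families, 2432 kept their direction and side of the threshold, 150 fell below it, 32 passed it and 18 reversed. DESeq2 left 188 of 194 values as they were, RLE scaling 194 of 198, no filter 194 of 198, microRNA scaling 141 of 180 and library totals 167 of 198. The cause was not tested except where fewer genes or libraries, or a stricter threshold, explain it by construction.

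With a mean of at least 50 counts, which tests fewer genes, the calls were 4597 in adult nip2nip3 against wt, 3937 in nip3_qe17, 255 in embryo input, 420 in the IP, 1246 and 1210 for IP against input in wt and nipnip2, and 16 for the difference of IP over input. RNA calls were 2 in the triple mutant, 2 in nip2_nip3, 3 in nip3_qe20, 0 in nip1_tb1601, 0 in nip2_tb1609 and 1 for the triple mutant against nip2_nip3, with 10 over the 6 genotypes in place of 34. Against a fold of 1.5, a stricter test, they were 3682, 3370 and 205 for nip2nip3, nip3_qe17 and their difference, 334 in embryo input and 13 for the difference of IP over input. Small RNA families gave 73 and 74 in the adult mutants, 5 in embryo input and 11 in the IP, and RNA families 5 in the triple mutant, 4 in nip3_qe20, 1 for the triple mutant against nip2_nip3, and 22 in sum.

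DESeq2 gave 338 genes in embryo input, 502 in the IP, 195 for the difference of IP over input, 6 small RNA families in embryo input, 5 RNA families in nip3_qe17 and 14 in nip3_qe20. With no low-count filter embryo input gave 1019 genes and the triple mutant 6 families, and RLE scaling gave 6 families in the triple mutant. A fit of only the groups compared gave 31 RNA families in the triple mutant, 4 in nip2_nip3, 0 in nip3_qe17, 1 in nip3_qe20, 28 in nip1_tb1601, 0 for the triple mutant against nip2_nip3 and 65 in sum. With all repeat families kept, embryo input gave 26 small RNA families, the IP 37, and RNA of the triple mutant 5. In 1 fit of all embryo libraries embryo input gave 5 families. Camera with an estimated correlation called 4 lists in place of 39.

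Scaling to microRNA reads gave 7070 genes in embryo input, 2031 in the IP, 9011 and 9027 for IP against input in wt and nipnip2 and 1 for their difference, with 140 and 85 families in input and IP. It reversed his-15 (0.36) and ergo-1 (1.43) in input, and Y37E11B.2 (0.042), prg-1 (2.16) and nrde-3 (1.79) in the IP. For wt IP against input it reversed F52D2.6 (-0.56), F55C9.5 (-0.18), C44B11.6 (-0.028), his-45 (-0.80) and nrde-3 (-2.98), and for nipnip2 nrde-3 (-3.0) and ergo-1 (-4.34). Library totals gave 1764, 2175, 8999, 8834 and 1645 genes in the same order, 72 and 86 families, and RNA families of 3 in the triple mutant, 2 in nip3_qe20, 0 in nip1_tb1601, 0 in nip2_tb1609, 0 for the triple mutant against nip2_nip3 and 14 in sum. They reversed prg-1 (1.92) and nrde-3 (1.64) in the IP, nrde-3 (-1.66) for wt IP against input, nrde-3 (-0.87) and ergo-1 (-2.22) for nipnip2, and linc-22 (1.0) for the difference of IP over input. In embryos the microRNA reads lay largely on mir-260 and cel-mir-8199, whose shares were higher in the wt IP and lower in nipnip2 input. The cause of these shifts was not tested.

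Leaving out 1 library gave 4435 to 6776 genes for nip2nip3 (4435 without wt 1), 3820 to 5978 for nip3_qe17 (3820 without wt 1), 372 to 657 for their difference (412 without nip2nip3 2, 372 without nip3_qe17 3), 610 to 921 in embryo input (921 without nip1nip1_1), 1380 to 2454 for wt IP against input (1380 without IP wt2) and 10 to 142 for the difference of IP over input (11 without IP wt1, 10 without IP nip1nip1_1, 14 without IP nip1nip2_2, 142 and 53 without the inputs of the last names). Families were 0 to 14 in embryo input (0 without wt1, 3 without nip1nip1_1, 7 without nip1nip2_2) and 8 to 32 in the IP (8 without wt2, 12 without nip1nip1_1). The ranges in the IP (683 to 843 genes) and for nipnip2 IP against input (1885 to 2659) stayed within 1.5 times of the main counts.

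For RNA families the ranges were 4 to 12 in the triple mutant (7 and 6 without its replicates 1 and 3, 4, 4 and 6 without wt 1, 2 and 3), 0 to 9 in nip3_qe17 (9 without its replicate 1, 1 without its replicates 2 or 3 or wt 1, 0 without wt 2 or 3), 0 to 8 in nip3_qe20 (4 without its replicate 2, 0 without each wt), 0 to 1 in nip1_tb1601 (0 without either of its libraries or wt 3, 1 without wt 1 or 2), 0 to 1 in nip2_tb1609 (0 without its replicate 2), 1 to 2 for the triple mutant against nip2_nip3 (1 without triple mutant 1, nip2_nip3 1 or 3) and 12 to 45 in sum (13, 12 and 13 without wt 1, 2 and 3). Where a group was left with 1 library, that library was assumed to vary like the others.

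The replicate number was not taken to pair the libraries, since not every pair of the same number had a correlation above 0.1. In adult small RNA 4 of 7 such pairs had one (median 0.115), against 1 of 14 pairs of different numbers (median -0.0623), and in RNA-seq 23 of 52 (median 0.0415) against 41 of 102 (median -0.0136). Single RNA-seq pairs ranged from -0.844 to 0.730 for the same number and from -0.734 to 0.844 for different numbers. Strong structure not tied to the number thus remained, and the RNA tests did not model it. With the replicate block nip3_qe17 gave 1 RNA family in place of 2, and no other count of calls moved by more than 1.5 times. The embryo columns do not carry the sample numbers, but input and IP columns share names. Columns of one name had a correlation of -0.0524 in wt and 0.129 in nipnip2, so the name was not taken to pair them either. With the name as a replicate block, IP against input gave 2214 genes in wt and 2694 in nipnip2, and the difference of IP over input gave 147 in place of 81, 80 of them shared.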

Other observations

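Fold changes in this part come from the tests of the report, no further test was made, and the values were chosen after they were seen. Small RNAs and RNA of the same families are set side by side. In nip2nip3 small RNAs at Turmoil2 rose by 1.60 on the log2 scale, and those at CER2-1-LTR_CE fell by 2.04. RNA of Turmoil2 fell in nip2_nip3 (log2 fold change -1.86, SE 0.34) and RNA of CER2-1-LTR_CE rose (log2 fold change 2.75, SE 0.55). These are single families, and over the 150 families no relation was called (rho -0.0725, permutation p = 0.376).

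Small RNAs at prx-11 were higher in nip2nip3 than in nip3_qe17 (log2 fold change 3.42, SE 0.11) and in nipnip2 embryo input than in wt input (log2 fold change 3.74, SE 0.31). An entry named piRNASensor in the embryo tables had 391 and 286 counts in wt input and 581 and 368 in nipnip2 input. The share of counts on microRNAs was 22.1 ± 0.356% in adult wt (SD, n = 2), 25.9 ± 0.101% in nip2nip3 (n = 3) and 25.4 ± 0.747% in nip3_qe17 (n = 3).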
